A study of Cyanidioschyzon merolae with 75 samples.

How the data were processed

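RNA of the unicellular red alga Cyanidioschyzon merolae, strain 10D, was measured on 75 two-colour arrays covering 25 sampling times from 2 to 50 h after light and dark cycles had set the culture in step. Each time appears in 3 series. Per the labels' protocols, total RNA was amplified from an oligo(dT) primer into amino-allyl RNA, the RNA of the sampling time carried Cy3, and a mixture of the samples carried Cy5. The dyes were assigned alike on all 75 arrays, so a dye bias of a gene is part of its ratio to the pool. Such a bias cancels in differences between times only where it is the same on every array, which was not tested. The clock hours of light and dark, the scanner and the handling of the background are not given in the sources used here.

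The deposited files hold raw Cy5 and Cy3 intensity values, Cy3 intensities scaled by the authors, the ratio of scaled Cy3 to Cy5 as the authors computed it, and a log2 value. In series 1 and 2, with 20 h left out, the deposited log2 value was compared with the deposited ratio. It equalled log2 of that ratio minus the mean of the probe over the 25 times of its series, with 1 scale factor per array. Series 3 was not compared in this way. Medians of these log2 values over probes, as deposited by the authors for series 3, ran from -0.30 at 28 h to 0.65 at 46 h. Scale, centring and direction were all settled by this comparison. Intensities were used on 73 arrays. The other 2, series 1 and 2 at 14 h, held only log2 values, which entered the comparison of columns and no fit. Fits with a series left out therefore lacked 14 h. In 74 of 75 samples the sample's log2 column equalled the series table within 1e-06. At 48 h in series 3 the sample's own column repeated 46 h at 100% of probes, so the series table was used there. At 20 h in series 1 the scaled Cy3 column repeated 18 h within 0.01 at 100% of probes, so raw intensities were used throughout the main analysis.

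The 3 series were compared before anything was averaged. At all 24 times with intensities in 3 series, 100% of series 3 intensities equalled the mean of series 1 and 2 within 0.01%. Series 1 and 2 carried 1 common scale factor, equal within 0.0001, at 23 of 23 times compared. The repeated column at 20 h was left out of that comparison, and the factors there were 0.640 and 0.653. Log2 ratios of series 1 and 2 differed with an SD of 0.043 to 0.123 over probes, median 0.088. The 3 series were therefore counted as 1 sample per time, represented by series 3, and no replicate culture enters any test. p-values measure the scatter of the times around a fitted curve or of matched times around their mean difference.

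Ratios were computed as Cy3 over Cy5 with limma 3.58.1 in R 4.3.3, normalised within each array by loess, and averaged over the probes of a gene. The design, the named-gene rule, the thresholds and the first set of alternatives were fixed before the data were examined. That plan set the normexp background correction for files with a background column, and the intensities used here have none, so they entered uncorrected. Normexp with an offset of 50, fitted to the intensities alone, had been run first and its larger counts had been seen before the setting went back to the wording of the plan. Its counts stand beside the main ones wherever they differ by over 1.5 times.

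The array held 4586 probes for 4576 genes. Of these, 10 genes had a second probe, and the correlation of the 2 probes over time ran from -0.12 to 0.72. It was above 0.5 in 3 of the 10, with a median of 0.10, so the averaged values of these genes are uncertain. Genes with 1 probe could not be checked in this way, so their values are not known to be sounder. Locus tags of 4565 genes matched the reference gene table of assembly ASM9120v1, and 11 did not match. That table pairs 0 genes with a symbol other than the tag, so genes are given by tag, and all 20 functional gene lists fixed in the plan had no matched member. The planned camera test of these lists was not run.

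The analysis departs from the plan where the series turned out to be 1 sample. The plan treated 75 arrays as separate values, and the main tests here use 1 value per time, which the plan had listed as the alternative. The planned F-test of any time effect has only the spread between readings of 1 sample as its error, so the main value for it is the number of genes with a range of at least 1 on the log2 scale. Apart from that, the named-gene rule asked for informative gene names and could be applied only in its other parts.

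Rhythm was tested with limma's moderated F-test of a cosine and a sine of 24 h over 25 values. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and a fitted peak-to-trough of at least 1 on the log2 scale. The level of the second cycle was compared with the first by limma's moderated test on 12 differences between times 24 h apart, with calls at an adjusted p under 0.05 and a 1.5-fold difference. A change of rhythm between cycles was tested with the moderated F-test of the interaction of cycle with cosine and sine over 24 values. Named genes are the 8 largest fitted peak-to-troughs with peaks within 4 h in every series, the 6 highest and 6 lowest level differences with 1 sign in every series, the 6 smallest interaction p-values and the 5 smallest p-values of the F-test over series.

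The fits were tested on simulated data with 4576 genes and the residual spread of each real gene. Recovered genes and false calls were counted at an adjusted p under 0.05 alone. The minimum peak-to-trough and fold difference of the calls were not applied there, so recovery under the full rules was not measured. For the rhythm, 100 of 100 genes with a peak-to-trough of 2 and 98 of 100 with 1.2 were recovered, with 11 false calls. For the level, 98 of 100 differences of 1 and 96 of 100 of 0.6 were recovered, with 14 false calls. For the change of rhythm, 92 of 100 rhythms of 2 and 80 of 100 of 1.2 present in 1 cycle were recovered, with 9 false calls. The simulated noise was independent between times and between genes, so the numbers of false calls hold for that case only. Alternatives covered background correction, normalisation, the authors' log2 values, a filter on dim probes, array weights, the series, the period, extra curve terms, single times left out, the brightest arrays and position along the probe order. Depth has no counterpart on arrays, and the number of arrays limits the precision.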

Results

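The series follows gene expression in synchronised cells through 2 cell cycles, sampled every 2 h from 2 to 50 h, with attention to the division of the cell and its organelles. Ratios of each sampling time to a pool of the samples were obtained for 4576 genes. Series 3 was the mean of the other series, which carried 1 common scale factor at 23 of 23 times compared, so the 3 series of a time were counted as 1 sample. Values carry fit errors and no replicate error. Median Cy5 intensity lay between 12093 and 14416 on the arrays of 2, 4, 6 and 26 h and between 552 and 4668 on the other 21.

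The times fell into an order that returned after about 1 day. The first principal component held 27.1% of the variance and the second 18.1%. Component 1 was positive at 12 to 18 h and at 32 to 44 h, and negative at 2 to 10 h, 20 to 30 h and 46 to 50 h. The mean correlation between arrays across genes was 0.50 at a separation of 2 h, -0.37 at 12 h, 0.17 at 24 h, -0.35 at 36 h and 0.42 for the 1 pair 48 h apart. Single pairs varied widely, from -0.004 to 0.90 at 2 h and from -0.15 to 0.44 at 24 h. At 22 h the mean was 0.17 as well. Genes are not independent replicates, so these correlations carry no test.

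**Figure D1:**
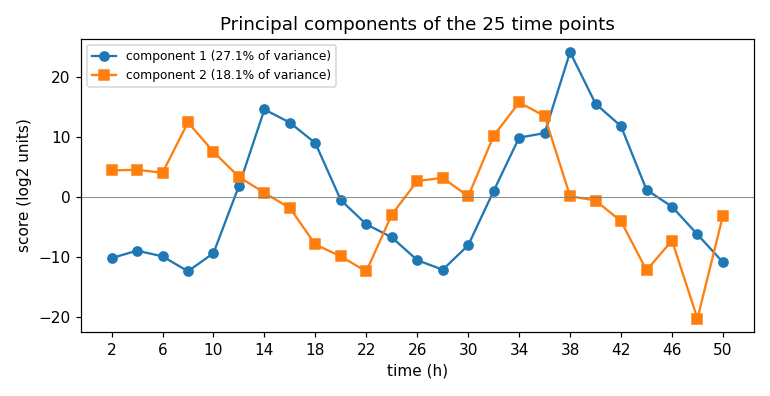
Scores of the first 2 principal components (log2 units) against time in hours, 1 point per sampling time. Component 1, with 27.1% of the variance, is highest at 14 h (14.6) in the first cycle and at 38 h (24.1) in the second.

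Measured ratios of many genes to the pool spanned 2-fold or more over the course. CMS022C spanned 6.88 on the log2 scale, from its lowest ratio at 10 h to its highest at 38 h, the widest range of the 4576 genes. CMT172C spanned 5.10, with its lowest value at 14 h and its highest at 48 h. CMP166C spanned 4.18, CMH047C 3.87 and CMN166C 3.67. A range of at least 1 was found in 1697 genes (37.1%) and of at least 2 in 339 (7.41%), and the median range was 0.82. The range has no replicate check, and the limma F-test over the series, in which 4576 of 4576 genes had an adjusted p under 0.05 on 73 arrays, measures times against repeated readings of 1 sample only. The count of genes with a range of at least 1 was 3881 with normexp and 3974 in the authors' log2 values.

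A 24 h rhythm was called in 234 genes (5.11%), and 38 of them had a fitted peak-to-trough of at least 2. CMS022C had the largest, 4.97 ± 0.67 (standard error of the fit, 25 times), with a fitted peak at 17.0 h. CMS101C followed with 4.29 ± 0.43 and a peak at 12.5 h. CMN263C and CMT504C peaked at 15.2 and 15.4 h with a peak-to-trough of 3.34 ± 0.42 and 3.17 ± 0.43. CMN235C (3.78 ± 0.37), CMN234C (3.31 ± 0.39) and CMQ142C (3.10 ± 0.46) peaked early, at 5.8, 6.4 and 6.3 h, and CMN234C and CMN235C carry adjacent tags. CMT172C peaked at 1.3 h, with 3.10 ± 0.39. Adjusted p-values from limma for these 8 genes ran from 2.07e-06 for CMN235C to 1.31e-04 for CMQ142C.

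**Figure D2:**
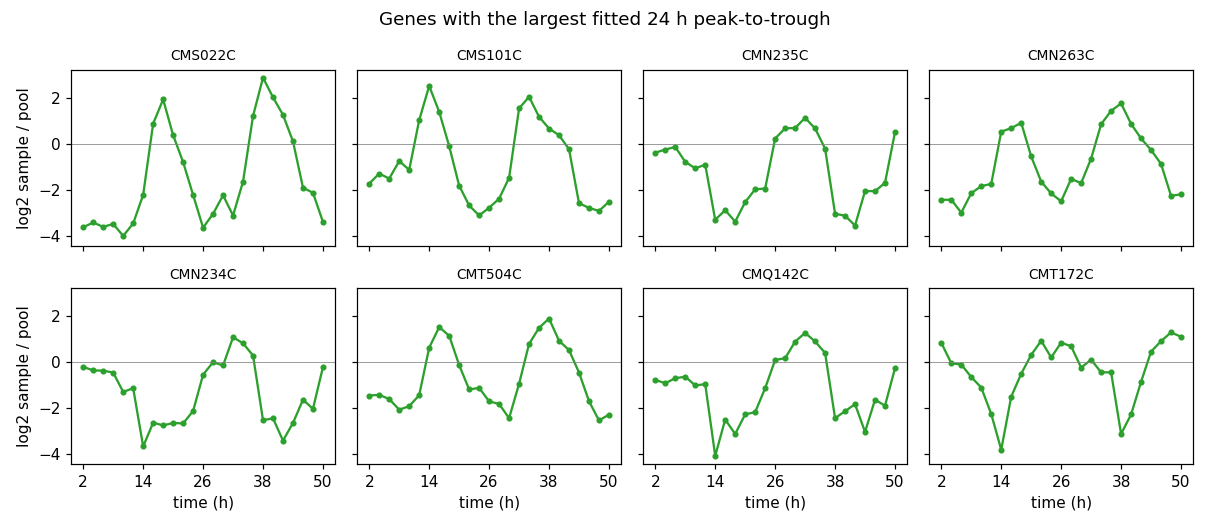
Log2 ratio of sample to pool against time in hours for the 8 genes with the largest fitted peak-to-trough, 1 point per sampling time and 1 panel per gene. CMS022C has the widest fitted rhythm, 4.97, and CMT172C has its lowest ratio at 14 h.

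A set of rhythmic genes stood close together in tag order. CMN145C, CMN165C, CMN166C, CMN169C, CMN173C and CMN176C, chosen after their values were seen, had peak-to-troughs from 2.49 to 3.07 and peaks from 15.6 to 16.2 h. Of the 25 genes measured from CMN145C to CMN176C, 7 were called, these 6 and CMN156C, which peaked at 11.5 h.

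**Figure D3:**
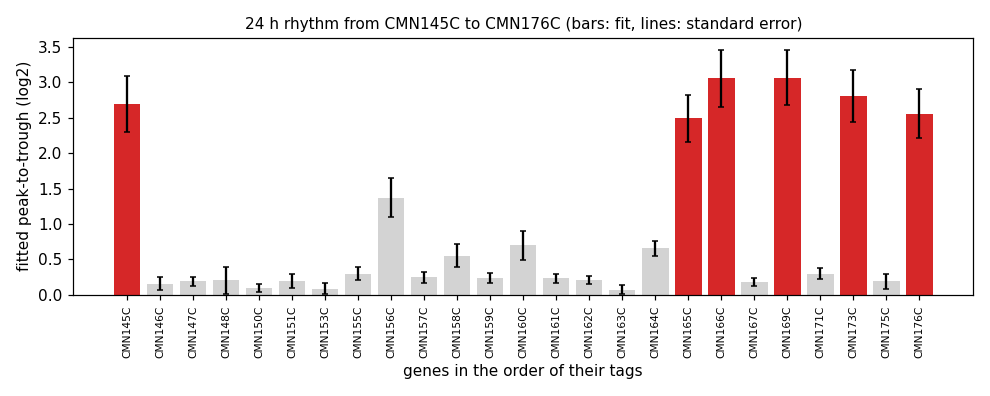
Fitted 24 h peak-to-trough (log2, bars from 0, lines for the standard error of the fit) of the 25 genes from CMN145C to CMN176C in tag order. The 6 genes in red lie between 2.49 and 3.07, and CMN156C, in grey, has 1.37.

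At an adjusted p under 0.05 alone, 1397 genes (30.5%) showed the rhythm. Across the 234 called genes the median peak-to-trough was 1.37, and the standard error of the peak time was 0.69 h in the median. Between 1 and 7 h 83 genes peaked, led by CMN235C, and between 7 and 13 h 59, led by CMS101C. Between 13 and 19 h 79 genes peaked, led by CMS022C, and 20 of these had a peak-to-trough of at least 2. Between 19 and 1 h 13 of the 234 peaked. This uneven spread holds for genes past the minimum peak-to-trough: the 1397 genes peaked throughout the day, with 82 to 156 in each bin of 2 h and 140 between 22 and 24 h. The called genes numbered 396 with normexp, and all 234 were among them. Adjusted p alone gave 1348 there. The list itself changed in other fits. Of the 234 genes, 137 were among the 210 called from 2 to 24 h alone. From 26 to 48 h alone, 182 of them were among the 306 called. Each of these fits holds 12 of the 25 times. Array weights kept 198 of the 234 among 215 calls. Every other setting kept at least 206 of the 234.

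**Figure D4:**
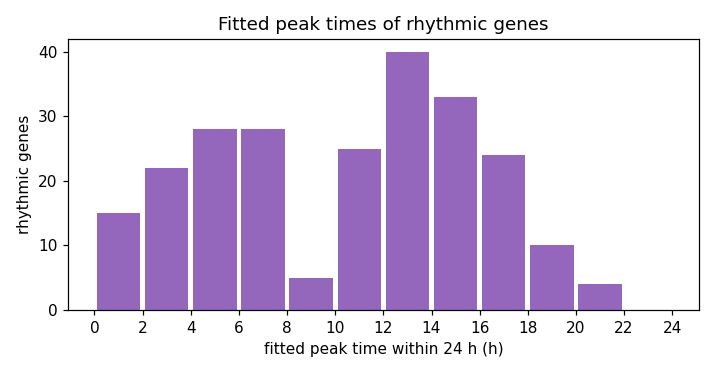
Number of rhythmic genes (bars, from 0) by fitted peak time within 24 h, in bins of 2 h. The fullest bin, 12 to 14 h, holds 40 genes, and the bin from 22 to 24 h holds 0, where 140 genes had an adjusted p under 0.05 without the minimum peak-to-trough.

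The rhythm returned in the second cycle. In 213 of the 234 genes (91.0%) the peaks fitted to each cycle lay within 4 h of each other, against 55.8% of all genes and 33.3% for unrelated times. Because the call used both cycles, each cycle was also taken alone. From 2 to 24 h 210 genes were called and from 26 to 48 h 306, with 104 in common where independent lists would share 14. That number draws from all 4576 genes, and is too low because only genes that vary widely can enter either list. In the first set 81.0% had their peak in the other cycle within 4 h, and in the second set 79.1%. The second cycle had the larger peak-to-trough in 71.8% of the 234 genes, with medians of 1.62 and 1.35. Array spread differed between the cycles. The SD of log2 ratios was 0.25, 0.22 and 0.23 on the bright arrays of 2, 4 and 6 h. It was 0.41, 0.41 and 0.47 at 38, 46 and 48 h. Against this, it was 0.42 at 8 h, 0.40 at 14 h and 0.23 on the bright array of 26 h. Array spread was not separated from the larger peak-to-trough. The median shift of the peak from the first to the second cycle was -2.42 h in genes peaking between 13 and 19 h and 0.94 h in genes peaking between 1 and 7 h. These shifts were not tested as groups.

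Other periods were fitted to see how sharply 24 h stood out. The number of genes with an adjusted p under 0.05 was 1397 at 24 h, 1339 at 23 h, 1350 at 25 h, 436 at 20 h, 886 at 28 h, 138 at 36 h and 170 at 48 h. At 10, 12, 14 and 16 h limma called 0 genes. A course of 50 h does not separate periods 1 h apart.

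**Figure D5:**
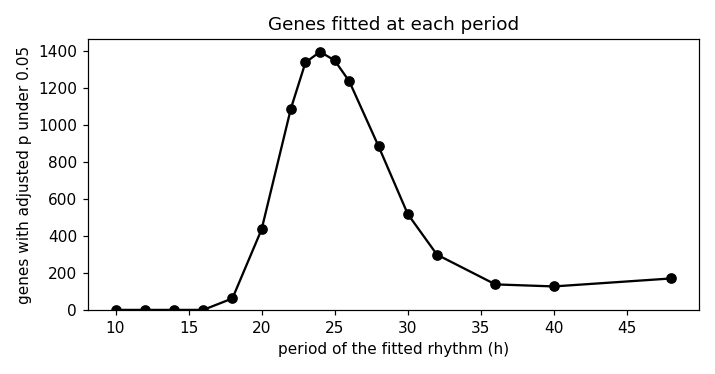
Number of genes with an adjusted p under 0.05 against the period of the fitted rhythm in hours, 1 point per period tried. The number is highest at 24 h, with 1397 genes, and 0 at periods of 10 to 16 h.

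The second cycle was compared with the first to ask which genes kept another level at matched times. Of 53 genes called, 41 were lower and 12 higher in the second cycle. CME183C fell by 1.17 ± 0.26 (log2, standard error, 12 matched differences) and CMC149C fell by 1.05 ± 0.23, each lower at 11 of 12 matched times. CMT162C fell by 0.98 ± 0.11, CMM003C fell by 0.94 ± 0.13 and CMQ293C fell by 0.89 ± 0.10, all lower at 12 of 12, and CME041C fell by 1.00 ± 0.16 at 11 of 12. CMI242C rose by 1.2 ± 0.26, CMS331C by 1.10 ± 0.23 and CMP166C by 1.05 ± 0.25, each at 11 of 12 matched times. CMQ142C rose by 0.92 ± 0.24 and CMF144C by 0.90 ± 0.18 at 10 of 12, and CMQ031C by 0.80 ± 0.21 at 9 of 12. The calls of CMQ142C, CMQ031C and CMP166C were lost in 28, 26 and 24 of 38 alternative fits, with median centring among them. CME183C lost its call in 13 of 38, CMC149C in 10, CMI242C in 6, and CMS331C and CMF144C in 2 each. The other 4 genes lost it in 0. Leaving out either time of a matched pair gives the same level fit, so each of the 12 pairs is counted 2 times among the 38. The calls of CMQ142C, CMQ031C, CMP166C and CME183C were lost with any 1 series left out. Those fits also lacked 14 h, and without 14 h alone these calls were lost as well. CMQ142C was 0.85 without series 3 and 0.85 without 14 h, so these losses cannot be put down to a series. Adjusted p-values from limma for these 12 genes ran from 5.93e-04 for CMT162C and CMQ293C to 0.0497 for CMQ031C.

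Of the 53 genes 12 were also rhythmic, and 831 genes had an unadjusted p under 0.05. The balance of higher and lower calls depended on the scaling. It was 12 higher to 41 lower here, 33 to 34 with scaling between arrays, 3 to 90 with median centring and 7 to 65 in the authors' log2 values. The calls numbered 110 with normexp, 34 without the times 8 and 32 h, and 91 without 24 and 48 h. Without the times that hold a bright array, 9 matched differences were left and 8 of the 12 named genes lost their call, while all 12 kept their sign. The difference was then 1.35 for CMI242C, 1.24 for CMP166C, 1.00 for CMS331C and -1.08 for CME183C, and the lowered ones included CMC149C at -0.75 and CMQ031C at 0.61.

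The rhythm itself differed between the cycles in 108 genes, of which 70 had the larger peak-to-trough in the second cycle and 38 in the first. Array spread was not separated from this split either. CMJ146C changed from 1.49 with a peak at 5.0 h to 0.77 with a peak at 15.5 h, counted within each cycle; this change of -0.72 was -0.32 without the bright arrays and -1.36 with median centring, still called in both. CMB155C went from 3.12 to 0.79 with its peak near 18 h in both cycles, at 18.3 and 17.6 h. CML063C went from 3.58 to 1.56, with the peak at 19.2 and then 14.7 h. CMG206C and CMO116C kept a similar size, 1.69 and 1.56 for CMG206C and 1.54 and 1.37 for CMO116C, and their peaks moved from 18.4 to 11.9 h and from 16.2 to 11.4 h. CMQ350C had 0.37 in the first cycle and 1.71 in the second, with the peak at 17.2 h in the latter; with median centring this change was 0.44 in place of 1.34, with an adjusted p of 0.065 from limma. The adjusted p of the limma interaction test was 9.28e-04 for CMJ146C and 0.00399 for CML063C, CMB155C, CMG206C, CMO116C and CMQ350C. Peaks lay over 4 h apart in 87 of the 108, and 23 were among the rhythmic genes. The number called was 33 with median centring, 167 with scaling between arrays, 64 in the authors' log2 values, 70 without the bright arrays and 236 with array weights. With single times left out it ran from 49 without 4 h to 139 without 26 h. When cycles were exchanged over runs of neighbouring matched times, 12 of 67 arrangements, the real one included, called at least 108 genes, and the highest other called 380.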

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

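The test of array position by the difference between repeated readings and the exchange of runs of neighbouring times were chosen after the result was seen. The other tests of this part were fixed before their result, but the bright arrays themselves were picked after the data were seen.

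The 24 h rhythm differed between the first and the second cycle in 108 genes by the interaction test, and for that reason the genes are listed here with the change of their peak time. The peak of the second cycle minus that of the first was 10.5 h for CMJ146C, -4.52 h for CML063C, -0.62 h for CMB155C, -6.58 h for CMG206C, -4.87 h for CMO116C and -6.22 h for CMQ350C. In 100 exchanges of cycle within matched times, the real one included, 2 called at least 108 genes, and the highest other exchange called 139. Exchanging single times breaks the likeness of neighbouring times, so runs of neighbouring matched times were exchanged as well: 12 of 67 arrangements, the real one included, called at least 108 genes, and the highest other called 380. Chance is not excluded for this count.

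Rhythmic genes with a fitted peak between 22 and 8 h numbered 93, and the bright arrays of 2, 4, 6 and 26 h lie in that part of the day. Without those 4 arrays 92.5% of the 93 genes kept an adjusted p under 0.05 and a peak within 4 h (86 genes, exact 95% interval 85.1 to 96.9%). The interval takes genes as independent, which they are not, so it gives no error for this share. The share itself argues against array brightness as the cause of most of these peaks. Of the other 141 rhythmic genes 133 kept both. No biological explanation was tested.

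Profiles of probes near each other in the order of their tags were more alike than distant ones, with a mean correlation across times of 0.066 for adjacent probes, 0.143 at 2 places and 0.0033 at 50 places. The highest of 200 shuffled orders was 0.013 for adjacent probes. The difference between series 1 and 2, which holds no difference between samples, had a correlation of 0.082 at 2 places against at most 0.0098 in 200 shuffled orders, so position on the array may contribute. Pairs 1 to 5 places apart whose genes lie on different chromosomes had a mean correlation of -0.025 (285 pairs, highest of 200 shuffled orders 0.054). All pairs at these distances had 0.089, and shared regulation of chromosomal neighbours could give that contrast. Adjacent probes, however, were less alike than probes 2 places apart. The difference between series 1 and 2 had the same order, 0.019 for adjacent probes against 0.082. Shared regulation cannot give that order in a difference between readings of 1 sample, which argues against it as the whole cause. The 285 pairs lie only where the tag order passes from 1 chromosome to the next, so they sample few places and share probes. The shares of array position and of shared regulation remain open, since the layout of the spots is not given in the sources used here.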

How the results depend on the processing

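Settings chosen after the data were seen are normexp, the bright arrays, single times left out and the trend along the probe order; all arrays as separate values was the fit of the plan. Genes with a range of at least 1 numbered 1697, 3881 with normexp and 3974 in the authors' log ratios. Rhythmic genes numbered 234, 396 with normexp and 1397 by adjusted p alone. Other settings gave 210 to 306 (137 to 233 of the 234 kept), and 222 to 249 without 1 time. Level calls numbered 53 (12 higher, 41 lower), 110 with normexp (30, 80), 93 with median centring (3, 90), 159 by adjusted p alone, and 96 with all arrays as separate values and with the replicate block (51, 45 in each). The split was 33 to 34 with scaling between arrays, 31 to 30 with array weights and 7 to 65 in the authors' log ratios. With a series left out, where 14 h was lacking too, level calls ran from 40 to 44, and without 14 h alone they numbered 42. With a matched pair left out they ran from 34 (8 and 32 h) to 91 (24 and 48 h, with 42 higher and 49 lower).

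Genes whose rhythm differed between cycles numbered 108, and 33 with median centring, 167 with scaling between arrays, 64 in the authors' log ratios, 236 with array weights, 2400 with all arrays as separate values, 2345 with the replicate block and 70 without the bright arrays. Fits on all arrays count repeated readings as samples, which lowers their error. With a time left out the number ran from 49 (4 h) to 139 (26 h), and was 66 without 6 h, 71 without 10 or 18 h, 56 without 20 or 40 h, 62 without 34 h, 70 without 38 h and 57 without 42 h. The change of peak-to-trough from the first to the second cycle turned positive in CMG206C, to 0.24 with median centring, 0.18 with array weights, 0.22 without 18 h and 0.05 without 48 h (lowest with a time left out -0.27, without 38 h). In CMO116C it was 0.10 with median centring and 0.036 without 14 h (lowest with a time left out -0.31, without 6 h). Without series 1, 2 and 3 it was 0.042, 0.025 and 0.034, in fits that also lacked 14 h, so this turn cannot be put down to a series. In CMJ146C it was -0.72, with -0.32 without the bright arrays, -0.46 with them as a block, -0.43 with the probe-order trend removed and -1.36 with median centring. Except where a construction is named, the cause was not tested. Rhythm calls of the named genes held in all 630 fits, and level calls of the named genes were lost in 111 of 456 fits with no change of sign. Among the 456 each matched pair left out is counted 2 times, since leaving out either of its times gives the same level fit. For the change of rhythm, 1 of 228 fits of the named genes lost its call, CMQ350C with median centring (0.44, adjusted p 0.065).

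Deviations of the series correlated between times from -0.09 to 0.14, over 0.1 in 8 of 276 pairs of times, so the series numbers share only a number and the block result is given for that reason alone. A scan batch and the gene lists were not run. The brightness of an array sets how far dim spots stand above background, which no column measures.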

Other observations

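The comparison of falls between neighbouring times and the choice of the 6 genes near CMN166C were made after the values were seen. Setting those 6 genes against genes with 2 probes and the exchange of runs of neighbouring times were also chosen after the result was seen. The other tests were fixed before their result, but removal of the probe-order trend was added after the data were seen.

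A group of genes fell steeply at the same place of each cycle. Between 12 and 14 h 39 genes fell by at least 2-fold, and between 36 and 38 h 89 did, with 25 genes in common where independent lists would share 0.76. The changes in the earlier and the later step were -3.12 and -2.83 on the log2 scale for CMQ142C, -2.53 and -2.81 for CMN234C, -2.39 and -2.83 for CMN235C, and -1.55 and -2.67 for CMT172C. Of the 25 genes 21 were called rhythmic. Rises of 2-fold in the same steps were found in 57 and 28 genes with 2 in common, where independent lists would share 0.35. The numbers for independent lists draw from all 4576 genes. Only genes that vary by 2-fold can enter such lists, so these numbers are too low for them. The step from 46 to 48 h had the most changes of 2-fold, 146 up and 212 down, and none occurred from 2 to 4 h or from 4 to 6 h, where all 3 arrays are bright. The SD of log2 ratios over an array ran from 0.22 to 0.47, the highest at 48 h, and was 0.40 at 14 h and 0.41 at 38 h and at 46 h. Array weights were 0.75 at 14 h, 0.62 at 38 h, 0.31 at 46 h and 0.39 at 48 h, with the lowest, 0.29, at 8 h. Differences in spread between arrays were not separated from the changes in any of these steps. The counts of changed genes have no replicate error.

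CMN145C, CMN165C, CMN166C, CMN169C, CMN173C and CMN176C shared 1 rhythm, with pairwise correlations over time from 0.945 to 0.994. After the trend along the probe order was removed their median peak-to-trough was 2.77, against 2.75 before. That trend was a running median of neighbouring spots, and only 7 of the 25 genes in this stretch were called. Its removal could take out only an effect shared by most neighbours in tag order. Array position stays open for the 6 genes, since the layout of the spots is not given. Differences between 2 of the 6 varied over time by more than 1.5 times the spread of repeated readings in 15 of 15 pairs, but that spread leaves out differences between probes. The SD of these differences was 0.143 to 0.432, and that between 2 probes of the same gene was 0.148 to 0.342, exceeded in 8 of the 15 pairs, so spots measuring 1 common set of transcripts stay open. Shared regulation of the 6 genes was not tested.

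Chance assignment was weighed for the other counts. Of 100 assignments of the sampling times, 1, the real one, called 234 rhythmic genes, and the highest other called 0. Of 100 exchanges of cycle within matched times, 1, the real one, called 53 genes by level, and the highest other called 1. Both schemes break the likeness of neighbouring times. When runs of neighbouring matched times were exchanged, 2 of 67 arrangements, the real one included, called at least 53 genes by level, and the highest other called 72. Arrays 2 h apart correlated at 0.50 on average, so assignments and exchanges of single times do not exclude chance for either count. No assignment that keeps neighbouring times together was run for the rhythm. A drift over the course stays open for the level count. For the rhythm, a linear trend in the fit gave 233 genes, 210 of them among the 234, and periods of 36 and 48 h gave 138 and 170 genes by adjusted p against 1397 at 24 h.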
